A study of Mus musculus with 4 samples.

How the data were processed

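Single-cell RNA sequencing was done on cranial neural crest cells of mouse embryos at embryonic days (E) 12.5 and 13.5. Wnt1-Cre2 is a Cre recombinase line active in the neural crest, and R26R-EYFP is a reporter that turns recombined cells and their descendants fluorescent, so that sorting on the reporter takes neural crest progeny and any other cell with a Wnt1-Cre2 history. The Meis2 conditional knockout (Meis2 cKO) carried 2 floxed copies of Meis2, a gene for a homeodomain transcription factor of the TALE class. The labels give the control genotype in different ways: as 1 floxed copy in the sample characteristics and design text, and as no floxed copy in the extraction protocol. Each of the 4 libraries pooled 3 heads of 1 genotype and stage, from which the brains had been separated, per the labels' protocols. Tissue was dissociated in 3 rounds at 37 °C, 61% of cells were reporter-positive during sorting and 98.3% after it, viability was 99%, and about 10000 cells per library were aimed at with 10x Genomics 3' chemistry version 3.1 and a second read of 90 bases.

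The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, which the authors made with STARsolo 2.7.3a on genome build GRCm38; Seurat 4.1.0 is named as well, per the submitters' processing notes. The annotation release and the part each tool played are not given in the sources used here. Each file lists 46983 gene IDs and 6794880 barcodes, the same list in all 4 libraries, so cells had not yet been called. Gene symbols were taken from the files. Positions and lengths came from GENCODE release M21 on GRCm38, in which 46488 of the 46983 IDs were found. Library totals ran from 84020525 to 96489767 UMIs.

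Cells were called in each library alone, as barcodes with at least the larger of 1000 UMIs and 10% of the 99th percentile UMI count of the top 10000 barcodes. That gave minima of 2302 UMIs (control E12.5), 2599 (Meis2 cKO E12.5), 3266 (control E13.5) and 3871 (Meis2 cKO E13.5), and left 11181, 9110, 8565 and 7523 barcodes in the same order. Cells needed at least 500 genes (0, 0, 9 and 5 barcodes failed) and at most 10% mitochondrial UMIs (15, 20, 16 and 3 failed). Doublets were scored by the share of simulated doublets among each cell's nearest neighbours, and the highest-scoring 0.8% per 1000 cells were removed, which took out 997, 661, 583 and 452 cells. No annotation of cells from the authors was used. Values were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes were chosen within libraries without Meis2, sex-linked, mitochondrial and ribosomal genes, and 30 principal components with 20 nearest neighbours were clustered with the Leiden method at resolution 1, with no integration. This gave 36 clusters of at least 20 cells.

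A cluster was called mesenchyme-like where at least 5 of the fixed mesenchyme markers were each detected in at least 40% of its cells and no other class had more markers among its top 10 genes by fold. Every other name needed at least 3 markers of the class among those top 10 genes. The detection rule was set after the data had been seen. Under it 20 clusters were mesenchyme-like, and all clusters without a name are reported as unnamed. The share of 1 further class and 1 gene of a cycling cluster are not reported here. The mesenchyme-like cells were clustered a second time without 729 genes, those called by genotype in any class tested, and cluster shares are compared between genotypes from this second clustering. Shares carry exact (Clopper-Pearson) 95% binomial intervals, levels exact 95% Poisson intervals, ratios of UMI levels exact conditional ones, and ratios of shares normal ones on the log scale. All of them cover counting error only, not the variation between embryos or pools.

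UMIs were summed per library over the cells of a class and tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with TMM scaling, filterByExpr (minimum count 10), and Benjamini-Hochberg adjustment at a false discovery rate of 0.05. With 1 library per genotype and stage, no test exists within a stage. The genotype difference was therefore fitted over all 4 libraries with stage as a block, and the stage difference with genotype as a block. That leaves 1 residual degree of freedom, and edgeR estimated infinite prior degrees of freedom for mesenchyme-like cells, so that every gene took the shared spread and a gene whose genotype difference disagreed between the stages was not penalised for it. P-values thus rest on a spread shared across genes and not on replicates of each gene. An interaction model has no residual degrees of freedom, so differences between the stages are values with no test. Leaving out a library leaves no residual degrees of freedom either. Swapping genotypes within stages gives 4 arrangements, so a two-sided permutation p cannot go below 0.5. Log2 fold changes per stage are on TMM-scaled log CPM with a prior count of 2, whereas levels, ratios and their intervals are of plain CPM, a gene's UMI count divided by the UMI total of the class in that library and scaled to 1 common total. At E13.5 the TMM scale put the median ribosomal protein gene at -0.71 and the plain scale at -0.43.

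The 31 gene lists, fixed beforehand, were tested in mesenchyme-like cells with camera from limma 3.58.1 (preset correlation 0.01, two-sided, Benjamini-Hochberg over the lists), with camera under an estimated correlation and with fry as alternatives. They cover patterning and TALE factors, tissue types of the face, markers of other cells that a sort could hold, signalling pathways, cell cycle and stress. Genes were named by a rule fixed beforehand. For genotype these are, at a mean of at least 20 CPM and without mitochondrial, ribosomal, haemoglobin, sex-linked and unnamed models, the 12 largest changes in each direction among called genes with 1 direction at both stages, filled up with the largest uncalled ones, plus Meis2 and up to 4 members per list. For stage the rule takes 8 per direction and for every other class 4 per direction. For the difference between stages it takes the 8 largest at a mean of at least 50 CPM. Genes named outside this rule are said to be chosen after their values were seen. Classes and clusters with at least 100 cells in every library were tested in the same way.

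The following alternatives were planned before the data were examined: DESeq2 size factors in edgeR, no filter on low counts, DESeq2 1.42.0, limma-voom, the older edgeR method, no block, 2 times the UMI minimum, a mitochondrial maximum of 5%, doublets kept, equal numbers of cells, subtraction of the profile of barcodes with at most 100 UMIs, every mesenchymal cluster weighted alike (16 of the 20, since 4 had fewer than 20 cells in a library), other Leiden resolutions, values centred per library, and thinning of each cell to 3871 UMIs. Weighted alike means that a cluster had the same weight in every library, namely its mean share over the 4 libraries. It does not mean that all clusters had equal weights. Haemoglobin was to scale the subtraction but gave an estimate of 202% in control E12.5, so 5% of counts was subtracted in all libraries. Added after the data had been seen were 1 UMI minimum for all libraries, cycling clusters left out, ribosomal protein, haemoglobin and sex-linked genes left out, clusters weighted alike for the stage difference, the second clustering, the level of Meis2 without the Hoxa2 and Meis1 cluster, and removal of a trend on gene length. That trend was a loess curve (span 0.5) on log2 exonic length over genes of at least 5 CPM, fitted without ribosomal protein genes; 99.6% of the tested genes had a length. The fit was tested on simulated counts for the real genes. The simulation gave every gene a dispersion of 0.02, independent counts, the same fold in both blocks and no length trend. The real libraries depart from this, so its counts of unchanged genes called are no error rate for the real calls. For genotype in mesenchyme-like cells (18407 genes) it recovered 25.4% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 100% of those changed 4-fold, with 9 unchanged genes called. For stage (18198 genes) the shares were 17.9%, 85.1% and 100%, with 8 unchanged genes called. Clustering and plots used Python 3.11.15 with scikit-learn 1.9.0, leidenalg 0.10.2, scipy 1.17.1 and matplotlib 3.10.9.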

Results

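The data comprised 4 libraries of sorted cranial neural crest progeny from mouse heads, 1 for each combination of genotype (control, Meis2 cKO) and stage (E12.5, E13.5), each a pool of 3 heads. The files held 96489767 UMIs for control E12.5, 84020525 for Meis2 cKO E12.5, 85848626 for control E13.5 and 85015760 for Meis2 cKO E13.5. Cell calling left 10169, 8429, 7957 and 7063 cells in that order, with medians of 6832, 7264, 7176 and 7617 UMIs and of 2636, 2765, 2747 and 3143 genes per cell. Median mitochondrial shares were 2.7%, 3.23%, 3.21% and 2.91%. There were no replicate libraries within a genotype and stage, so intervals around single values cover counting error only. The pools also differed in sex: UMIs of the Y-linked genes Ddx3y and Eif2s3y were at 0 CPM in mesenchyme-like cells of control E12.5, against 29.6 and 40.9 CPM in Meis2 cKO E12.5, 51.0 and 64.7 CPM in control E13.5, and 58.0 and 59.2 CPM in Meis2 cKO E13.5.

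Most sorted cells were mesenchyme-like, with clusters of osteogenic character (led by Alpl, Runx2 and Sp7) and chondrogenic character (led by Hapln1, Col9a3 and Matn1) among them. Mesenchyme-like cells made up 60.5% of control E12.5 (95% interval 59.6 to 61.5), 62.8% of Meis2 cKO E12.5 (61.7 to 63.8), 87.5% of control E13.5 (86.7 to 88.2) and 82.2% of Meis2 cKO E13.5 (81.3 to 83.1). Unnamed clusters held 35.3%, 33.7%, 8.17% and 12.2% of cells in that order, and were led by neural genes such as Npy, Lhx9, Hes5 and Otp. Epithelium-like cells, with Epcam and keratins, were 1.68%, 1.32%, 1.76% and 2.62%. Sensory neuron-like cells with Isl1 and Neurod1 were 1.37%, 1.44%, 0.603% and 0.552%. The sort, the dissection of the brain and the UMI minimum of each library can all set such shares.

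Over all mesenchyme-like cells, Meis2 transcripts were somewhat less abundant in the Meis2 cKO libraries at both stages, though not in every cluster and in part with the makeup of the class. Mesenchyme-like cells held Meis2 at 340.2 CPM (95% Poisson interval 334.9 to 345.5) in control E12.5 and 275.4 (270.5 to 280.4) in Meis2 cKO E12.5, a ratio of 0.810 (0.791 to 0.829). At E13.5 the levels were 252.0 (247.9 to 256.2) and 220.7 (216.8 to 224.7), a ratio of 0.876 (0.855 to 0.897). The genotypes held unlike shares of a cluster rich in Meis2, led by Hoxa2, Meis1 and Meis2, which was 10.0% of these cells in control and 5.73% in Meis2 cKO at E12.5 and 7.34% and 1.91% at E13.5. Without that cluster, an alternative chosen after the data were seen, the ratio was 0.867 (0.843 to 0.891) at E12.5 and 1.01 (0.985 to 1.04) at E13.5. These ratios are of plain CPM, and the TMM factors of the E13.5 libraries, 0.978 in control and 1.18 in Meis2 cKO, would put the last below 1. In the test over all 4 libraries Meis2 did not pass in mesenchyme-like cells (log2 fold change -0.41, SE 0.22, adjusted p = 0.478). The gap was widest in the chondrogenic cluster, where the ratio was 0.545 (0.366 to 0.804) at E12.5 and 0.395 (0.329 to 0.473) at E13.5 and Meis2 passed (log2 fold change -1.30, adjusted p = 6.5e-05), the only one of the 14 classes and clusters tested in which it did. Within the Hoxa2, Meis1 and Meis2 cluster the ratio was 0.979 (0.930 to 1.029) at E12.5 and 0.978 (0.899 to 1.062) at E13.5, and in epithelium-like cells it was 1.0 (0.902 to 1.11) and 0.770 (0.688 to 0.861). The ratio was below 1 at both stages in the cycling cluster led by Cenpa and Cdc20, at 0.834 (0.776 to 0.895) and 0.80 (0.705 to 0.906), in that led by Hist1h1b and Hist1h2ae, at 0.653 (0.578 to 0.737) and 0.758 (0.659 to 0.872), and in the Mecom cluster, at 0.768 (0.703 to 0.838) and 0.820 (0.720 to 0.932). In the Crym and Gata2 cluster it was so at E13.5 alone, at 0.646 (0.518 to 0.804). At E12.5 alone it was so in the Foxf1 and Foxf2 cluster, at 0.886 (0.810 to 0.969). The cycling cluster led by Hist1h1b and Top2a was also below 1 at E12.5 alone, at 0.790 (0.656 to 0.949). All cells outside the mesenchyme were at 0.738 (0.715 to 0.761) at E12.5 and 0.932 (0.878 to 0.990) at E13.5. On plain CPM Meis2 was more abundant in Meis2 cKO in the Dcn and Pax1 cluster, with ratios of 1.83 (1.59 to 2.10) at E12.5 and 1.14 (1.06 to 1.21) at E13.5. At E13.5 it was so too in the Bambi and Hey2 cluster, at 1.65 (1.25 to 2.20), and in the Hic1, Nrk and Pitx1 cluster, at 1.17 (1.02 to 1.34). In the TMM-scaled tests over 4 libraries these 3 clusters gave log2 fold changes of 0.36, 0.13 and -0.02, none of which passed (adjusted p from 0.513 to 0.993). Meis2 (ENSMUSG00000027210.20) lies on the minus strand of chromosome 2 from 115863064 to 116065839 in GRCm38. The sources used here do not name the floxed exons, and the last of the 12 exons of its principal transcript, at 115863064 to 115864513, can still give 3' tags if it lies outside the deleted part. The level of Meis2 therefore does not check the genotype labels.

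**Figure D1:**
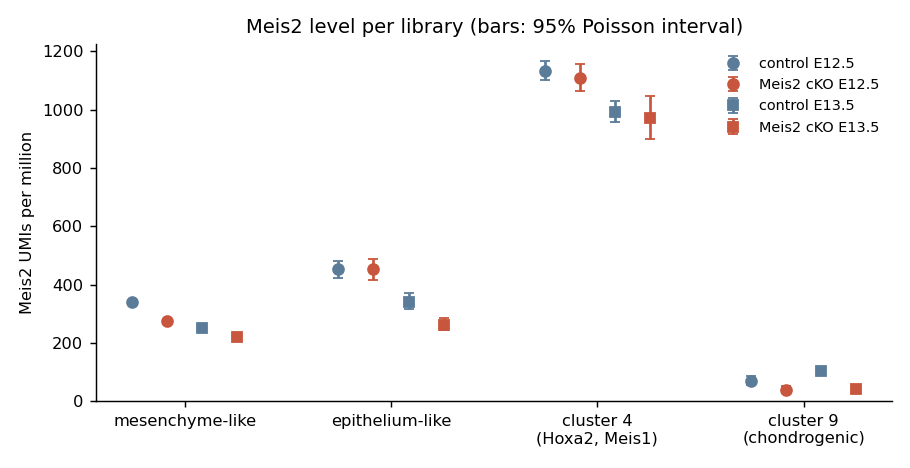
Meis2 level in CPM (y axis) in each library for 4 groups of cells (x axis); points are libraries and bars are 95% Poisson intervals of counting error. In the chondrogenic cluster both Meis2 cKO libraries lie below both control libraries, while the 4 libraries of the Hoxa2 and Meis1 cluster lie between 970.6 and 1134.2.

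To ask which genes depend on Meis2 in facial mesenchyme, genotypes were compared over both stages in mesenchyme-like cells. Lower in Meis2 cKO were Asb4, which encodes an ankyrin repeat protein of a ubiquitin ligase complex, the cartilage matrix gene Matn1, the angiotensin receptor gene Agtr2, the growth factor gene Nrtn (neurturin) and the immediate early gene Fos. With clusters weighted alike Agtr2 did not pass (below). Nrtn was among the top genes of the Cdkn1a and Sox18 cluster, which held a smaller share of both Meis2 cKO libraries (below). Asb4 (ENSMUSG00000042607.15, chromosome 6, 5383386 to 5433022) stood at 48.2 CPM in control and 29.0 CPM in Meis2 cKO at E12.5 and at 24.4 and 12.1 CPM at E13.5 (log2 fold change -1.03, SE 0.18, adjusted p = 2.9e-06). Matn1 (chromosome 4, 130944385 to 130955475) fell with a log2 fold change of -0.93 (SE 0.19, adjusted p = 7.0e-04), from 2.77 to 1.06 CPM at E12.5 and from 49.7 to 39.6 CPM at E13.5. Higher in Meis2 cKO were Tnks, which encodes the poly-ADP-ribose polymerase tankyrase (log2 fold change 0.64, SE 0.18, adjusted p = 0.0397), and the linker histone gene Hist1h1a (0.64, SE 0.18, adjusted p = 0.0496). Both were close to level at E12.5 (0.14 and 0.14) and higher at E13.5 (1.14 and 1.13).

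Of 18501 genes tested in mesenchyme-like cells, 72 rose and 95 fell in Meis2 cKO. Of these 167 genes, 57 were higher and 85 lower at both stages, and 25 went in opposite directions. Most calls were of weakly expressed genes, since 23 had a mean of at least 20 CPM. Agtr2 (log2 fold change -0.74), Nrtn (-0.73), Bex4 (-0.68), the snoRNA host gene Snhg3 (-0.65), Rpgrip1 (-0.65), the RNA polymerase II subunit gene Polr2l (-0.63) and S100a13 (-0.63) fell with adjusted p between 0.00884 (Agtr2) and 0.0432 (S100a13). Fos fell as well (-0.87, adjusted p = 0.00182). AA465934, a noncoding transcript on chromosome 11 from 83291699 to 83294632, had the largest change by this rule (-2.71, adjusted p = 5.9e-31), and 1 library set it: control E12.5 was at 155.5 CPM and the other 3 were at 6.19, 5.89 and 4.67 CPM. Thbs2, Gata2, Npnt, Six2, Scube1, Adamts9, Pdzd2, Spaca6, Tbx3os1 and Mir6236 were higher at both stages without passing, with log2 fold changes from 0.39 (Pdzd2, adjusted p = 0.396) to 0.63 (Thbs2, adjusted p = 0.0564). Rpa3 was lower at both stages (-0.58 and -0.57, adjusted p = 0.118). DESeq2 called 7 genes and limma-voom 66. The 7 genes that all 3 tools called, chosen after their values were seen, were Asb4, Cartpt, C1ql3, Junb, Sox18, Onecut2 and Psd, and all of them were lower at both stages. The 3 tools used the same sums of counts, so their calls in common do not set aside the makeup of the class. C1ql3 and Sox18 were among the top genes of clusters that held smaller shares of both Meis2 cKO libraries (below). Among the 7 genes Cartpt, which encodes a neuropeptide precursor, stood at 3.82 CPM in control and 0.347 CPM in Meis2 cKO at E12.5. At E13.5 it stood at 5.80 and 0.644 CPM.

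Long genes ran higher and short genes lower in both Meis2 cKO libraries. Over 6560 genes, which are not independent replicates, Spearman's rho between the genotype log2 fold change and exonic length was 0.41 at E12.5 and 0.65 at E13.5. The shortest 1 of 10 equal groups of genes by length had a median of -0.15 at E12.5 and -0.51 at E13.5, and the longest 0.05 and 0.33. The 16 fallen genes of at least 20 CPM had a median exonic length of 970 bases. It was 4539 for all 6648 tested genes of that level and 2068 for the 7 risen ones. Not all risen genes were short. Among them Hist1h1a, at 741 bases, ran against the trend, and Tnks, at 14888, went with it. The named higher genes that did not pass held long ones, such as Pdzd2 (18419) and Adamts9 (15048), and short ones, such as Six2 (2119). Over all levels the medians were 2230 for the 72 risen and 2001 for the 95 fallen genes. With the length trend removed, an alternative chosen after the data were seen, edgeR called 1 gene (Cartpt, adjusted p = 0.0145), with 1790 at an unadjusted p under 0.05. All 167 genes kept their direction, and the median log2 fold change went from 1.28 to 1.45 for risen genes and from -1.46 to -1.29 for fallen ones. The prior degrees of freedom went from infinite to 8.23, and what ended the calls was not tested.

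**Figure D2:**
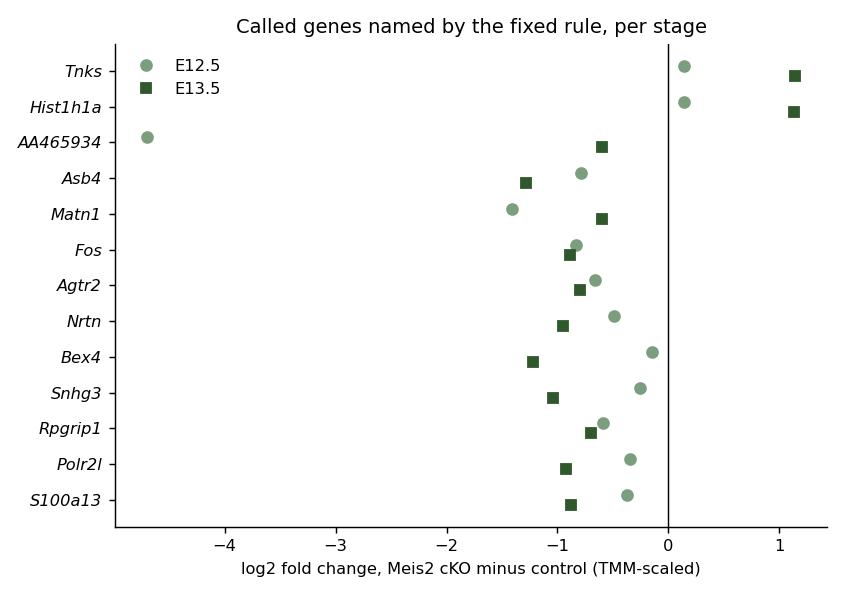
Log2 fold change between Meis2 cKO and control (x axis, TMM-scaled) at each stage for the genes (y axis) that were named by the fixed rule and passed the test over 4 libraries in mesenchyme-like cells; circles are E12.5 and squares E13.5. Tnks and Hist1h1a lie near 0 at E12.5, and AA465934 lies at -4.70 at E12.5 and -0.60 at E13.5.

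**Figure D3:**
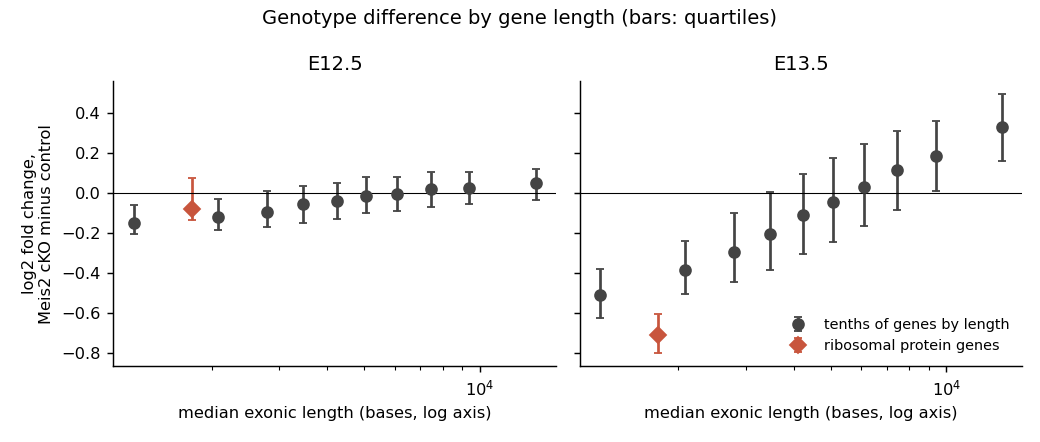
Median log2 fold change between Meis2 cKO and control (y axis) for 10 equal groups of genes by exonic length (x axis, log scale, bases) at each stage, with bars from the lower to the upper quartile; the diamond is the set of 82 ribosomal protein genes. The medians climb from -0.15 to 0.05 at E12.5 and from -0.51 to 0.33 at E13.5.

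Among the gene lists for skeletal tissue, the osteoblast list was higher in Meis2 cKO (camera, adjusted p = 0.0148; adjusted p = 0.957 with an estimated correlation), and over all cells it did not pass (adjusted p = 0.0708). Of its 17 measured members, 2 rose and 1 fell, and 3 rose and 1 fell when adjusted over the list alone. Ibsp, the gene for bone sialoprotein (chromosome 5, 104299171 to 104311469), rose with a log2 fold change of 1.70 (SE 0.21, adjusted p = 1.9e-12), but its levels were 0.493 CPM in control and 11.6 CPM in Meis2 cKO at E12.5 and 105.9 and 124.3 CPM at E13.5. Smpd3, a sphingomyelinase gene needed for mineralisation, rose (0.77, adjusted p = 0.00915), and Spp1, the osteopontin gene, fell (-0.91, adjusted p = 0.00303). Runx2, the master factor of osteoblasts, was at 0.61 without passing (adjusted p = 0.0569). The cartilage list did not move as a whole (adjusted p = 0.779): of 18 members Matn1 alone fell over all genes, and 2 rose and 2 fell when adjusted over the list alone. With each mesenchymal cluster weighted alike in every library, the cartilage list was lower (adjusted p = 1.7e-04) and the osteoblast list stayed higher (adjusted p = 0.00308). Neither passed with an estimated correlation (adjusted p = 0.960 for both). With these weights the osteoblast median was 0.17 at E12.5 and -0.02 at E13.5.

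The list of tongue and mandibular mesenchyme factors was lower in Meis2 cKO (adjusted p = 0.0131; adjusted p = 0.957 with an estimated correlation). Of its 11 members 2 fell, and 3 when adjusted over the list alone. These were the jaw factor gene Hand1 (-1.47, adjusted p = 0.00109), at 1.86 CPM in control and 0.202 CPM in Meis2 cKO at E13.5, and the forkhead gene Foxf2 (-0.65, adjusted p = 0.0466). The Hox list was higher (adjusted p = 0.0301; adjusted p = 0.957 with an estimated correlation), with 1 of 8 measured members risen, or 3 when adjusted over the list alone, and over all cells it did not pass (adjusted p = 0.742). The median of the Hox list was -0.42 at E12.5, the other way, and 0.73 at E13.5. The risen gene, Hoxb1 (chromosome 11, 96365752 to 96368256), had 3.61 CPM in Meis2 cKO E13.5 and at most 0.123 CPM in the other libraries. Hoxb3 and Hoxb4 were at 9.22 and 6.35 CPM in Meis2 cKO E13.5 against 2.39 and 1.60 CPM in control E13.5. With clusters weighted alike neither list passed (adjusted p = 0.536 for tongue and mandible and 0.425 for Hox), nor with the length trend removed (adjusted p = 0.0855 and 0.0513). The other 5 called lists still passed without that trend, and the S phase list then passed as lower (adjusted p = 0.00972). With an estimated correlation none of these lists passed without that trend (adjusted p = 0.825 for each). The palate gene Sim2 fell (-1.08, adjusted p = 1.6e-04) and so did the tendon gene Thbs4 (-0.89, adjusted p = 0.00123), the endothelin receptor gene Ednrb (-0.94, adjusted p = 0.0111) and Cdkn1a, which encodes the cell cycle inhibitor p21 (-1.33, adjusted p = 1.2e-08). Cdkn1a stood at 19.7 CPM in control and 4.83 CPM in Meis2 cKO at E12.5 and at 16.8 and 13.1 CPM at E13.5. Thbs4 is the leading gene of a cluster that held a smaller share of both Meis2 cKO libraries (below). With clusters weighted alike Thbs4 (-0.07, adjusted p = 0.913), Agtr2 (-0.25, adjusted p = 0.627), Foxf2 (-0.46, adjusted p = 0.369), Hand1 (-0.81, adjusted p = 0.390) and Ednrb (-0.56, adjusted p = 0.408) did not pass, while Sim2 and Cdkn1a did.

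Lists of other cells and of tissue handling moved with genotype too. The dissociation stress list was lower in Meis2 cKO (adjusted p = 5.0e-08; adjusted p = 0.957 with an estimated correlation), with Junb and Fos fallen among 18 members, and 6 fallen when adjusted over the list alone. The median of this list was level at E12.5 (-0.01) and lower at E13.5 (-0.77). Junb went from 1.37 to 0.855 CPM at E12.5 and from 35.6 to 15.5 CPM at E13.5. The endothelium list was lower (adjusted p = 9.0e-09; adjusted p = 0.957 with an estimated correlation; 3 of 10 fallen, and 4 over the list alone), with Cdh5 at 1.34 CPM in control E13.5 and 0.202 CPM in Meis2 cKO E13.5. The macrophage list was lower (adjusted p = 3.5e-04; adjusted p = 0.957 with an estimated correlation), with 1 of 10 fallen, and 4 over the list alone, and Pf4 at 3.99 and 1.51 CPM at E13.5. With cycling clusters left out, Pf4 turned to a log2 fold change of 1.88, so its direction depended on which clusters were summed. Over all cells the macrophage list was higher in Meis2 cKO (adjusted p = 6.0e-07, and 0.963 with an estimated correlation), with 1 of 10 risen, and 3 over the list alone. Its median over all cells was 2.02 at E12.5 and -0.43 at E13.5, so it was higher at E12.5 alone. The erythroid list was lower (adjusted p = 1.5e-61; adjusted p = 0.957 with an estimated correlation), with 6 of 10 fallen, and 9 over the list alone, but its median was -10.70 at E12.5 and 2.20, the other way, at E13.5. A few cells set both: 7 cells of control E12.5 held 88303 of the 88515 haemoglobin UMIs of its mesenchyme-like cells, and 3 cells of Meis2 cKO E13.5 held 18863 of 20034. None of the 31 lists passed in fry (smallest adjusted p = 0.503 for direction and 0.586 for either direction). Both fry and camera with an estimated correlation rest on 1 residual degree of freedom, so they could hardly pass any list. The erythroid list went from an unadjusted camera p of 5.0e-63 to 0.113 with an estimated correlation. Not passing in these alternatives therefore says little about a list.

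The other 24 lists did not pass. Adjusted p was 0.938 for TALE homeobox genes, 0.916 for jaw patterning factors, 0.806 for tooth mesenchyme, 0.938 for palate mesenchyme, 0.938 for tendon and 0.303 for collagens and matrix. Among signalling lists it was 0.938 for BMP, 0.952 for WNT, 0.777 for Hedgehog, 0.799 for FGF, 0.0573 for retinoic acid, 0.777 for Notch and 0.916 for TGF-beta. Over all cells the retinoic acid list (adjusted p = 0.0186) and the neuronal list (adjusted p = 0.00367) were lower in Meis2 cKO (adjusted p = 0.963 with an estimated correlation for both). The all-cell medians of the retinoic acid list were -0.02 at E12.5 and -0.35 at E13.5, and those of the neuronal list 0.01 and -0.23. In mesenchyme-like cells adjusted p was 0.190 for S phase, 0.938 for G2 and M phase, 0.165 for p53 targets and 0.385 for hypoxia and glycolysis. Lists of other cell types gave 0.573 for smooth muscle and mural cells, 0.799 for the Schwann lineage, 0.938 for pigment cells, 0.927 for neurons, 0.375 for skeletal muscle and 0.777 for epithelium. For jaw patterning, tooth, tendon, BMP, WNT, Hedgehog, FGF, and G2 and M phase the median, the mean and the direction of the test did not all share a sign. Within these lists Myog (1.87, adjusted p = 0.00123) and Neurod1 (1.26, adjusted p = 0.0489) rose, both with their highest level in Meis2 cKO E13.5 (2.48 and 2.71 CPM) and at most 0.601 CPM elsewhere. Rbp4, a retinol carrier gene, was at -0.84 without passing (adjusted p = 0.0564), and Crabp1, the most abundant member of the retinoic acid list, at -0.44 (adjusted p = 0.514).

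Genotypes were also compared within single clusters, with no test between clusters, and in most of them DESeq2 called no gene. In the cluster led by Foxf1, Foxf2 and Pax9, Gsc, a homeobox gene of jaw patterning, fell (-1.50; 78.1 to 36.7 CPM at E12.5 and 59.9 to 17.1 CPM at E13.5), as did Pcp4 (-2.26) and Asb4 (-1.53), and Matn4 (1.21), Scube1 (1.19), Fat3 (1.21) and Car2 (1.25) rose. In the chondrogenic cluster Matn1 (-1.14) and the BMP antagonist gene Sostdc1 (-1.41) fell and Ttr (6.22; 2.74 to 239 CPM at E13.5), Tubb3 (1.35) and Cxcl14 (1.08) rose. Over all mesenchyme-like cells at E13.5 Ttr was at 46.0 CPM in control and 41.9 CPM in Meis2 cKO, so its rise there was not general. Whether a few cells, doublets or free RNA set the level of Ttr in the chondrogenic cluster was not tested. Cxcl14 was higher at E12.5 (3.79) and level at E13.5 (0.03), and Sostdc1 differed mainly at E13.5 (-0.25 at E12.5 and -1.49 at E13.5). In the cluster led by Hic1, Nrk and Pitx1, the nuclear receptor gene Nr5a2 fell (-1.94; 37.0 to 9.58 CPM at E12.5 and 32.2 to 9.80 CPM at E13.5), with Igfbp7 (-2.63) and Lpl (-1.61). In all, 21 genes rose and 26 fell in that cluster. In the cluster led by Mecom, the homeobox gene Msx2 fell (-1.85; 24.6 to 4.1 CPM at E12.5 and 59.5 to 25.4 CPM at E13.5) and Calca, Crh and Sfrp1 rose (1.84, 1.75 and 0.96). In the Hoxa2 and Meis1 cluster C1ql3 (-1.42), Tac1 (-1.44) and Sparcl1 (-1.65) fell and Luzp2 (1.61) and Maob (1.09) rose. In the cluster led by Cxcl14, Lhx8 and Tbx18, Foxd1 (-1.44), En1 (-1.05) and Ebf3 (-0.98) fell and Kera (1.15), Ndnf (1.01) and Itga4 (1.33) rose. Foxd1 differed mainly at E13.5 (15.7 to 14 CPM at E12.5 and 54.4 to 16.3 CPM at E13.5). AA465934 fell in all 14 classes and clusters tested.

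In a cycling mesenchymal cluster led by Hist1h1b, Ibsp (2.11) and Smpd3 (1.97) rose, among 24 risen and 22 fallen genes. In another, led by Cenpa and Cdc20, Sox6 rose (1.01) and Gng11 fell (-1.20). In the third cycling cluster tested, led by Hist1h1b and Top2a, Foxd1 (-1.38), Sox18 (-1.18) and Nrtn (-1.13) fell and Smoc2 (1.28) rose. In the Dcn and Pax1 cluster Cxcl13 (-2.51) and Ramp3 (-1.88) fell and Sim1 (1.23) rose; in the Bambi and Hey2 cluster Pitx1 (-1.46) and Nts (-0.94) fell and Sst (1.47) and Penk (1.10) rose; and in the Crym and Gata2 cluster Bex4 fell (-0.79) and Ttr rose (4.84). Of these, Ttr (5.37 and 0.51) and Sst (2.92 and 0.13) were higher mainly at E12.5, and Ramp3 was lower at E13.5 (-0.18 and -2.14). Epithelium-like cells had lower Lhx2 (-1.61; 69.0 to 9.43 CPM at E12.5 and 44.9 to 30.2 CPM at E13.5), Neurod1 (-1.45) and Pcp4 (-1.25) and higher Sparcl1 (2.18) and Nrp2 (1.17). In all cells outside the mesenchyme, Cnpy1 (2.05), En2 (1.62) and Lhx9 (1.43) rose and Hoxb9 (-1.44), Hoxc6 (-1.40) and Hoxb5os (-1.26) fell. Calls per class ranged from 22 in the chondrogenic cluster to 166 outside the mesenchyme, and DESeq2 called 23 genes in all 14 together. Over all cells 75 genes rose and 111 fell of 19931 tested, and without a filter on low counts 11 rose and 6 fell.

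To ask whether the makeup of the mesenchyme differed, mesenchyme-like cells were clustered without the genes called by genotype. Clusters marked by Thbs4, Hand2 and Foxf2, by C1ql3 and Tac1, and by Hoxa2 and Meis2 held smaller shares of both Meis2 cKO libraries. The Thbs4 and Hand2 cluster was 6.42% of mesenchyme-like cells (5.82 to 7.06) in control and 2.97% (2.53 to 3.46) in Meis2 cKO at E12.5, and 7.17% (6.57 to 7.80) and 1.27% (1.0 to 1.6) at E13.5. The C1ql3 and Tac1 cluster was 3.35% (2.91 to 3.83) and 1.70% (1.37 to 2.09) at E12.5, and 4.96% (4.46 to 5.49) and 0.947% (0.714 to 1.23) at E13.5. The Hoxa2 and Meis2 cluster was 6.21% (5.62 to 6.84) and 3.84% (3.34 to 4.39) at E12.5, and 0.474% (0.327 to 0.665) and 0.121% (0.0485 to 0.248) at E13.5. The osteogenic cluster was larger in Meis2 cKO at E13.5, at 8.80% (8.08 to 9.56) against 5.92% (5.38 to 6.5), and at E12.5 its intervals overlapped, at 1.23% (0.949 to 1.56) and 0.796% (0.589 to 1.05). This gap depended on the settings. As shares of all cells, osteogenic cells at E13.5 were 8.92% (8.31 to 9.57) of control and 10.3% (9.62 to 11.1) of Meis2 cKO in the first clustering. They were 10.9% (10.0 to 11.8) and 11.9% (10.8 to 13), which overlap, with 2 times the UMI minimum, and 11.4% and 23.4% at Leiden resolution 0.5. The chondrogenic cluster led by Hapln1 had overlapping intervals at both stages, at 1.23% (0.974 to 1.54) and 1.38% (1.08 to 1.73) at E12.5 and 5.23% (4.72 to 5.78) and 6.03% (5.43 to 6.67) at E13.5. Another chondrogenic cluster, led by Mia, Sox9 and Sox5, was larger in Meis2 cKO at E12.5, at 5.10% (4.53 to 5.73) against 3.77% (3.31 to 4.27), and had overlapping intervals at E13.5. The share of chondrogenic cells among all cells at E13.5 was larger in Meis2 cKO under some settings, at 15.4% against 10.3% at Leiden resolution 2 and 12.1% against 9.93% with values centred per library. Clusters marked by Col12a1 and Alcam and by Galntl6 and Otor came mostly from Meis2 cKO E13.5, with 8.66% and 5.89% of its mesenchyme-like cells against 1.36% and 1.21% of control E13.5, and may be that library and not a cell type. With 1 library per genotype and stage no share has a test.

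**Figure D4:**
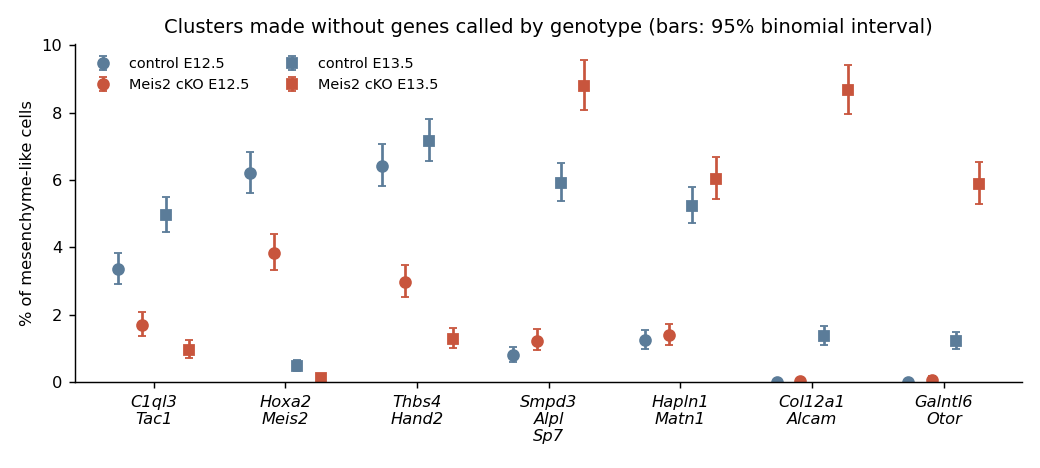
Share of mesenchyme-like cells (y axis, percent) in 7 clusters (x axis, named by leading genes) made without the genes called by genotype; points are libraries and bars are 95% binomial intervals. The C1ql3, Hoxa2 and Thbs4 clusters lie lower in Meis2 cKO at both stages, and the Smpd3 cluster is at 8.80% in Meis2 cKO E13.5 against 5.92% in control E13.5.

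Between E12.5 and E13.5 the largest differences in mesenchyme-like cells, 8 in each direction by the fixed rule, were of the genes below, and no gene list was tested by stage. Ibsp rose with a log2 fold change of 4.91 (SE 0.22, adjusted p = 2.2e-101), and among the top genes of the chondrogenic cluster Matn1 (4.44), Col11a2 (2.91), Cytl1 (2.90) and Hapln1 (2.79) rose. The immediate early genes Fos (5.39, SE 0.22, adjusted p = 3.4e-129) and Egr1 (3.72) rose as well, Fos from 1.84 to 84.1 CPM in control and from 1.06 to 54.9 CPM in Meis2 cKO. Not every gene of these kinds did so: Spp1 (-0.10, adjusted p = 0.772), Bglap (-1.10, adjusted p = 0.189) and the immediate early gene Ier2 (0.17, adjusted p = 0.536) did not pass. Ttr, the transthyretin gene, rose (3.39), from 0.407 to 46.0 CPM in control and from 14.2 to 41.9 CPM in Meis2 cKO. Histone genes Hist1h4d (-1.86), Hist1h3e (-1.58), Hist1h4h (-1.51), Hist2h2bb (-1.39) and Hist1h2bj (-1.36) fell, with Hddc3 (-2.03), Atp5k (-1.37, adjusted p = 2.0e-05) and AA465934 (-2.86), the last set by control E12.5. In all, 2499 genes rose and 1566 fell of 18501. DESeq2 size factors in edgeR gave 2242 and 1753, DESeq2 itself 1012 and 1168. Stage also goes with the pool, the library and the sex of the embryos, which 1 library per genotype cannot separate from it.

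The genotype difference was not alike at both stages. Across genes the log2 fold changes at E12.5 and E13.5 had a correlation of 0.103 (genes are not independent replicates). Ibsp was far higher in Meis2 cKO at E12.5 and level at E13.5 (4.40 and -0.04, a difference of -4.44 with a counting interval of -5.05 to -3.84). At E13.5 the actin gene Actg1 (143.4 and 525.9 CPM), the cadherin gene Cdh2 (51.4 and 124.6 CPM), Adnp, Erbb2ip and Usp9x were higher in Meis2 cKO by log2 fold changes of 1.0 (Usp9x) to 1.60 (Actg1), and Stmn1 (382.0 and 186.5 CPM) and Bex4 were lower (-1.31 and -1.22), while at E12.5 all 7 lay between -0.18 and 0.06. By exonic length, the higher genes Usp9x (15051 bases), Cdh2 (8066) and Erbb2ip (7939) went with the length trend at E13.5. So did the lower and short genes Stmn1 (1922) and Bex4 (837). Adnp (5350) lay near the middle of the trend, and Actg1 (2658) went against it. The 82 ribosomal protein genes took 22.7% of UMIs in control E12.5, 22.6% in Meis2 cKO E12.5 and 22.7% in control E13.5, but 17.1% in Meis2 cKO E13.5, where all 82 were lower. None of these differences between stages was tested.

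At E13.5, but not E12.5, more mesenchyme-like cells of Meis2 cKO than of control held transcripts of the cycling genes Mki67 or Top2a. S phase genes took 2873 CPM in control E12.5, 2872 in Meis2 cKO E12.5, 2174 (2162 to 2186) in control E13.5 and 2413 (2400 to 2426) in Meis2 cKO E13.5. G2 and M phase genes took 3819, 3873, 3116 (3101 to 3131) and 3412 (3396 to 3427). Members differed in direction: in plain CPM at E13.5 Mki67 was at 73.5 in control and 132.4 in Meis2 cKO, but Birc5 at 189.7 and 146.7, Cks2 at 76.6 and 54.4, Tubb4b at 172.9 and 135.4 and Tyms at 114.1 and 98.9. Mki67 has 10061 exonic bases, and long genes ran higher in that Meis2 cKO library, so the share of cells with its UMIs may follow length and not cycling. The sums above are of plain counts; on the TMM scale the median S phase gene was lower in Meis2 cKO at E13.5 (-0.11) and the median G2 and M phase gene was level (0.02). Cells with a Mki67 or Top2a UMI were 31.9%, 33.0%, 26.0% and 30.5% of mesenchyme-like cells, whose median depths were 7079, 7548, 7142 and 7687 UMIs. Thinned to 3871 UMIs per cell, after leaving out 175, 79, 212 and 0 shallower cells, the shares were 25.6% (24.5 to 26.8), 25.7% (24.5 to 26.9), 20.3% (19.3 to 21.2) and 23.4% (22.4 to 24.6). In sensory neuron-like cells, taken as a type with little division, the thinned shares were 11.5% (6.72 to 18), 16% (9.90 to 23.8), 6.25% (1.31 to 17.2) and 7.69% (1.62 to 20.9) at median depths of 10215, 12200, 11843 and 12020 UMIs. The last pair rest on 3 cells each, and dividing precursors among these cells were not ruled out, so the background is known only loosely.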

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

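No test was chosen for this part after its results were seen, and none of the differences below was tested: each is a value whose genotype difference, Meis2 cKO against control, had opposite signs at the 2 stages, and on plain CPM or as a share did so beyond counting error at both. That need not hold on the TMM scale of the log2 fold changes below. A model with an interaction has no residual degrees of freedom, and each stage has 1 library per genotype.

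In mesenchyme-like cells the log2 fold change of Ttr, the transthyretin gene, was 4.95 at E12.5 and -0.41 at E13.5, a difference of -5.36. The histone gene Hist1h4d went from 0.12 to -0.74, a difference of -0.86, and Hist1h3e from 0.22 to -0.62, a difference of -0.84. The actin gene Actg1 went from -0.11 to 1.60, a difference of 1.71, and the cadherin gene Cdh2 from -0.17 to 1.0, a difference of 1.17. Des, a muscle filament gene, went from -0.92 to 0.17, a difference of 1.09, at levels of at most 2.72 CPM. Id1, a BMP target, was level at E12.5 on this scale and went from 0.00 to -0.73, a difference of -0.73.

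The haemoglobin genes Hbb-y and Hba-a1 gave differences of 14.56 (from -14.06 to 0.51) and 12.76 (from -10.65 to 2.10). These depend on the prior count, since Meis2 cKO E12.5 held 10 haemoglobin UMIs in all, and on 7 cells of control E12.5 that held 99.8% of its 88515. The share of mesenchyme-like cells was 2.23 percentage points higher in Meis2 cKO at E12.5 and 5.27 points lower (-5.27) at E13.5, a difference of -7.50 points, which the sort and the dissection of each pool can set.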

How the results depend on the processing

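Chosen after the data were seen were 1 UMI minimum for all libraries, cycling clusters left out, ribosomal protein, haemoglobin and sex-linked genes left out, weighting for the stage difference, the second clustering, Meis2 without the Hoxa2 and Meis1 cluster, and removal of the length trend. The 167 genotype calls in mesenchyme-like cells were 7 with DESeq2, 66 with limma-voom, 98 with clusters weighted alike, 0 with no block (134 genes at an unadjusted p under 0.05) and 1 with the length trend removed. DESeq2 size factors in edgeR gave 148, of which 52 rose and 96 fell, against 72 and 95. The 186 calls in all cells were 17 with no filter on low counts, 13 with DESeq2, 85 with limma-voom, 0 with no block (105 at an unadjusted p under 0.05) and 14 with the length trend removed. The 4065 stage calls were 2180 with DESeq2 and 1170 with no block. Calls in the other classes came to 23 with DESeq2, and the 7 lists to 0 with an estimated correlation, which rests on 1 residual degree of freedom. Removing the block puts the stage difference into the spread of the genotype fit, and the genotype difference into that of the stage fit. Removing the length trend went with fewer prior degrees of freedom, smaller median fold changes of fallen genes and larger ones of risen genes. The cause was not tested for any setting. Of 34 named genes called by genotype, DESeq2 size factors kept 32, limma-voom 17, DESeq2 2, and both no block and removal of the length trend 0; none of these settings turned a direction. With cycling clusters left out Pf4 turned to 1.88, and the cause was not tested. Of 16 named stage genes, 14 passed with DESeq2 and with no block, 15 with the length trend removed, and 16 in every other setting.

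The ratio of Meis2 at E12.5 was 0.782 in all cells. Without the Hoxa2 and Meis1 cluster it was 0.867 at E12.5 and 1.01 at E13.5. With 2 times the UMI minimum mesenchyme-like cells were 61.7% of control E12.5, 63.9% of Meis2 cKO E12.5, 86.7% of control E13.5 and 83.8% of Meis2 cKO E13.5. With doublets kept they were 59.4% of control and 61.4% of Meis2 cKO at E12.5, and with a mitochondrial maximum of 5% they were 64.3% of Meis2 cKO E12.5. Thinning put cells with a Mki67 or Top2a UMI at 25.6%, 25.7%, 20.3% and 23.4%, since shallower cells show fewer genes. No paired analysis was possible because each group held 1 library, beyond the pairing of genotypes within stages by the block. Leaving out a library left no residual degrees of freedom. Depth limits weak genes most, and 23 of the 167 calls had a mean of at least 20 CPM.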

Other observations

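The tests of a trend on gene length, as the whole or a part of the lower ribosomal protein genes, and of those genes at E12.5 were chosen only after the results were seen; the other tests below were set before theirs.

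Some named members of the signalling and facial lists differed at E13.5 in both directions, and none of those given here passed over the 4 libraries. In the retinoic acid list, 3 of 15 members fell when adjusted over the list alone, and Cyp26a1, which encodes a retinoic acid degrading enzyme, was at 3.74 CPM in control and 1.40 CPM in Meis2 cKO at E13.5 (5.55 and 6.47 CPM at E12.5). Dhrs3, a retinaldehyde reductase gene, was at 19.5 and 13 CPM at E13.5. The Notch target Hes1 was at 106.6 and 88.4 CPM at E12.5 and at 63.3 and 43.3 CPM at E13.5, and the FGF antagonist Spry2 at 22.2 and 15.3 CPM at E13.5. In the other direction, the frontonasal factor Alx1 was at 203.9 and 240.8 CPM at E12.5 and at 132.3 and 292.5 CPM at E13.5, and the WNT antagonist Sfrp1 at 92.0 and 173.5 CPM at E13.5.

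Other mesenchymal clusters made without the called genes also held unlike shares at E13.5, with those given here chosen after their shares were seen. The Cdkn1a and Sox18 cluster was 7.17% of control (6.57 to 7.80) and 4.65% of Meis2 cKO (4.12 to 5.22), the Nefl, Ramp3 and Dlk1 cluster 6.57% (6.0 to 7.17) and 2.43% (2.05 to 2.86), and the Pitx1 and Nr5a2 cluster 1.59% (1.31 to 1.92) and 0.551% (0.377 to 0.777). At E12.5 the first was lower in Meis2 cKO as well, at 0.910% (0.688 to 1.18) of control and 0.397% (0.246 to 0.606) of Meis2 cKO, the second had overlapping intervals, and the third went the other way, at 3.12% (2.7 to 3.58) of control and 4.25% (3.72 to 4.83) of Meis2 cKO. The Hoxd1, Dcn and Pax1 cluster was larger in Meis2 cKO, at 10.1% (9.36 to 10.9) against 7.46% (6.85 to 8.10), and so was the Kera and Tbx18 cluster, at 3.77% (3.30 to 4.29) against 1.94% (1.63 to 2.29). Models annotated as sense intronic or to be experimentally tested, 502 in number, had medians of 0.26 at E12.5 and 0.50 at E13.5, and 423 of them were higher in Meis2 cKO at E13.5. Among cells outside the mesenchyme the isthmus genes En2 and Cnpy1 were at 7.41 and 5.74 CPM in control and 46.5 and 38.1 CPM in Meis2 cKO at E12.5.

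The 82 ribosomal protein genes were lower in Meis2 cKO at E13.5, with a median log2 fold change of -0.71. The intervals in this paragraph, and that of the slope for Ibsp below, come from 2000 bootstrap draws of genes. Genes are not independent replicates, so these intervals do not cover variation between libraries or embryos. A different mixture of clusters is argued against, because weighting clusters alike left -0.70 (bootstrap interval -0.72 to -0.66), and so is an effect of genotype alike at both stages, because the median at E12.5 was -0.079 (-0.11 to -0.04). Removing the length trend raised the median by 0.34 (0.30 to 0.36) and left -0.39 (-0.43 to -0.33), so the trend may be part of the cause. Whether it is the whole cause cannot be told. A first bound on the value left, written before it was seen, was neither met nor excluded. The interval lay below a second bound, but that bound was set after the value was seen. Exonic length also counts every annotated exon of a gene and not the transcript expressed, so the trend may be removed only in part. The library itself and an effect of genotype at E13.5 alone stay open, untested, since 1 library carries the pattern.

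Cells of the Hoxa2 and Meis1 cluster were fewer in Meis2 cKO at both stages. Clustered without genes that changed with genotype, the 2 matching clusters held 9.55% and 5.54% of mesenchyme-like cells at E12.5. At E13.5 they held 5.43% and 1.07%, and the larger ratio was 0.580. They were matched by their cells, of which 93.5% and 82.6% came from the first cluster. Of their top 10 genes, 6 and 5 were still genes called by genotype. The gap thus held, but clusters drawn by such genes are not excluded. Unequal UMI minima are argued against, since with 1 minimum the larger ratio was 0.605 (0.529 to 0.693). Less tissue from the back of the head cannot be told apart from an effect of genotype: unnamed, mostly neural cells with a UMI of Hoxb5 to Hoxb9 also had ratios below 1, of 0.838 (0.781 to 0.90) at E12.5 and 0.517 at E13.5, and each pool was dissected once. A loss of these cells in Meis2 cKO may thus be real or a matter of dissection. At E13.5 it may also be a matter of the library, since the Col12a1 and Galntl6 clusters came mostly from Meis2 cKO E13.5 (above). At E12.5 those clusters held 0.0189% and 0.0567% of mesenchyme-like cells of Meis2 cKO. Whether cells moved between clusters was not tested.

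Ibsp was higher in Meis2 cKO than in control at E12.5, with 11.6 and 0.493 CPM. Free RNA taken up by all cells is argued against, since 358 of its 501 UMIs lay in the osteogenic cluster, 35 times (32.9 to 36.9) that cluster's share of UMIs. More cells of the osteogenic cluster are argued against as the whole cause, since within it the ratio was 25 (13.4 to 52.5). There were 10 UMIs in 80 control cells, 2 of which held any. The 96 Meis2 cKO cells held 358, in 27 of them. More Ibsp-expressing cells inside the cluster are not excluded. The interval takes UMIs as independent, though few cells held them, and so is too narrow. Slightly older embryos in the Meis2 cKO pool cannot be told apart from earlier bone formation: across 4064 genes called by stage the slope of the E12.5 genotype difference on the stage difference was 0.073 (0.045 to 0.101), too close to both bounds set beforehand. Either may account for it.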
